A study of Mus musculus with 10 samples.

How the data were processed

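Skin of Tsk2 mice was profiled on 2-colour microarrays at 1 and 4 months of age. Tsk2 is a tight-skin mouse used as a model of scleroderma, and the gene mutated in it is Col3a1. Per the labels, total RNA was isolated with a kit for fibrous tissue, and 200 ng of each RNA was labelled with Agilent Quick-Amp chemistry. Skin was in Cy3 on every array, and a reference RNA named UMR in the labels was in Cy5. No dye swap was recorded in the labels. Wild-type skin was not analysed here, so age was the only labelled contrast between groups.

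The deposited table holds 41174 probes on 10 arrays, as log2 ratios of the 2 dyes made by the authors. Background correction, normalization and the scanner software are not given in the sources used here. The log base was read from the values. Of 190 pairs among the 20 commonest values of an array, 3 to 7 differed by the log2 of a small whole-number ratio within 0.0011, against a mean of 0.71 to 1.71 for shifted targets, 0 to 2 pairs for the natural logarithm and 0 to 3 for log10. Log10 equalled log2 on the second array of 4-month sample 2, so log2 is likely rather than certain. The median of every deposited column was 0, because 26.0% to 47.4% of an array's probes held an exact 0. These zeros were read as not measured. In the 2 samples with 2 arrays, 1307 to 8438 probes were at 0 on one array and measured on the other, where 3.75% to 9.18% had a log2 ratio over 2 in size. Their median size there was 0.047 to 0.481, so many zeros may stand for small ratios, and keeping the zeros was an alternative. Without the zeros, 21665 to 30425 values remained per array, with medians between -0.13 and 0.07, and genes were not centred.

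The deposited table does not name the numerator, so the direction of the ratios is likely rather than stated. Skin genes were negative in the deposited sign, and the sign was therefore turned so that a positive value reads as skin above reference. After turning, the median of the epidermal differentiation list lay between 4.02 and 4.82, and that of the skeletal muscle list between 3.90 and 6.47, above 0 on all 10 arrays. The cell division list lay between -2.73 and -0.47 and the B cell list between -4.33 and -0.60, below 0 on all 10 arrays. The rule fixed for this choice also asked for liver and embryo or testis genes on the opposite side. Their medians were near 0, above it on 5 arrays and below it on 5, and decided nothing. Under that rule no direction would have been given. The B cell and cell division lists were taken in their place after the values were seen. If the numerator were the other dye, every rise below would read as a fall and every fall as a rise, with the same sizes and tests.

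Probes were named from the platform annotation. Of the 41174 probes, 32664 had 1 gene symbol, 45 had several and 8465 had none, and only the first kind was used. Symbols were looked up by gene number in the RefSeq gene table, which held 32524 of the probes and changed no symbol. Both arrays of a sample were averaged where 2 had been run, which left 8 skin samples, 4 per age. A gene was the mean of its probes, with a probe and sample fit in place of single missing values. A probe and a gene needed a value in at least 3 samples of each age, which left 13501 genes.

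Ages were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with statmod 1.5.0, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Titles give each sample an ID number and a suffix. Samples of 1 number may come from 1 animal or litter, so the number was a random block through duplicateCorrelation, with a consensus correlation of 0.313. The 1-month samples carried 2 numbers and the 4-month samples 3, and no number occurred at both ages. Age cannot be told apart from any other difference between these numbers. Nothing in the labels says that samples came from separate animals, so p-values measure the spread between these samples, which may be partly technical. With 4 against 4 the smallest two-sided exact permutation p is 0.0286, and with 2 against 3 it is 0.1.

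The design, the alternatives, 41 gene lists and the rule for named genes were fixed before the data were examined. Lists covered matrix, hair follicle, epidermis, fat, muscle, immune cells, vessels, nerve, metabolism and sex chromosomes. Of the 1150 list entries, 1064 matched a probe. The 2 lists of sex-chromosome and liver genes had fewer than 5 measured members and were not tested, which left 39. Lists were tested with cameraPR at a preset correlation of 0.01, with camera at an estimated correlation on the 12397 genes measured in all 8 samples, and with fry. Counts of list members past the test are given over all genes tested and adjusted over the list alone. A list mean per sample was compared between ages with a two-sided exact permutation test over the 8 samples. Named genes were the 10 largest rises and 10 largest falls among genes past the threshold whose ages did not overlap, passing over clone and model names. Col1a1, Col1a2 and Col3a1 were always named, with up to 4 members of each list that passed and up to 2 members of each other list. Further keratins after the first 3 ranks were passed over.

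The fit was tested on simulated data for the comparison of 4 months against 1 month, with the real means, spreads, missing values and block correlation of 13501 genes and 200 changed genes (100 of each size). Of genes changed by 1 on the log2 scale 19% were recovered, and of genes changed by 2, 65%, all with the right sign and with 5 false calls. In the simulation a cell division list moved by -1 passed and 0 of the 38 other lists did, with genes simulated as independent of each other. Alternatives left out the block, averaged samples of 1 ID number, added the suffix as a replicate block, changed the arrays, scaling, filters and probe rule, and left out each sample in turn. Keeping the zeros, leaving out values shared by at least 100 probes of an array, covariates for Xist and for the skeletal muscle list, and leaving out 2 samples were added after seeing the data. The number of samples and of ID numbers limits the precision, and signal over background was not analysed here. Tables were made with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.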

Results

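Gene expression was measured in Tsk2 mouse skin against a common reference RNA on 10 arrays, 5 per age. They represent 4 skin samples at 1 month and 4 at 4 months, because 1 sample of each age was run on 2 arrays. The comparison asks how the skin transcriptome of this scleroderma model differs between the ages, and it cannot separate the mutation from age. No ID number occurred at both ages, so the comparison cannot separate age from other differences between those numbers either. All values are log2 ratios of skin over reference, in the likely direction set by skin, muscle, B cell and cell division genes, and with the other direction every rise would read as a fall. Arrays of the same sample correlated across probes at 0.901 and 0.910. The median correlation was 0.861 (range 0.752 to 0.928) between samples of 1 ID number, 0.839 (0.754 to 0.880) within an age across numbers, and 0.716 (0.663 to 0.811) between ages. Genes are not independent replicates in these values. The first principal component held 48.2% of the variance and separated the ages, from -52.60 to -22.31 at 1 month and from 7.96 to 55.65 at 4 months. On the second, with 17.2%, 1-month sample 2 (-57.39) and 4-month sample 3 (-26.79) stood apart. Both had ID suffix 2, as did 1-month sample 4 but no other 4-month sample. Outside the alternatives the fit held no term for the suffix.

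The largest rise from 1 to 4 months was in Nmrk2, a nicotinamide riboside kinase of muscle, which was higher by 4.87 ± 0.58 on the log2 scale (SE, 4 samples per age, adjusted p = 0.00464). Pdk4, the kinase that restrains pyruvate oxidation, was higher by 4.17 ± 0.35 (adjusted p = 0.00216). Asb2 (3.94), the purine enzyme gene Adssl1 (3.80), the heat shock gene Hspa1l (3.79), Klhl30 (3.74), the phospholipase gene Pla1a (3.61) and Fn3k (3.55), which repairs glycated proteins, also rose. Prkaa2, a catalytic subunit of AMP-activated kinase, rose by 3.49 with 3 samples measured per age, and Padi2 by 3.46. The largest fall was in Slc24a5, a melanosome ion exchanger, at -4.44 ± 0.33 (adjusted p = 0.00192). It was followed by Mycn (-3.89), Tgm6 (-3.79), Dlx2 (-3.62), B3galt5 (-3.41) and the fibrillar collagen gene Col11a1 (-3.37). Hunk (-3.36), Bambi, a decoy receptor of TGF-beta signalling (-3.30), the zinc transporter gene Slc39a10 (-3.26) and Ptgds (-3.26) fell as well. These 20 genes were chosen among those whose ages did not overlap. The calls of Bambi and Dlx2 were lost without 1-month sample 1 (adjusted p = 0.059 and 0.0594) and that of Prkaa2 without 1-month sample 2 (0.065). Prkaa2 had no value in that sample, so its call was lost through the refit of all genes and not through a value left out. Without a sample that held its value the gene was not tested. The same held for Hspa1l and Tgm6 at 4 months, where each had values in 3 samples. Padi2 lost its call without 1-month sample 1 or 2 or 4-month sample 1, 2 or 3 (adjusted p from 0.0646 to 0.083), and Col11a1 without 1-month sample 1 or 2 or 4-month sample 1 or 2 (from 0.0523 to 0.0859).

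**Figure D1:**
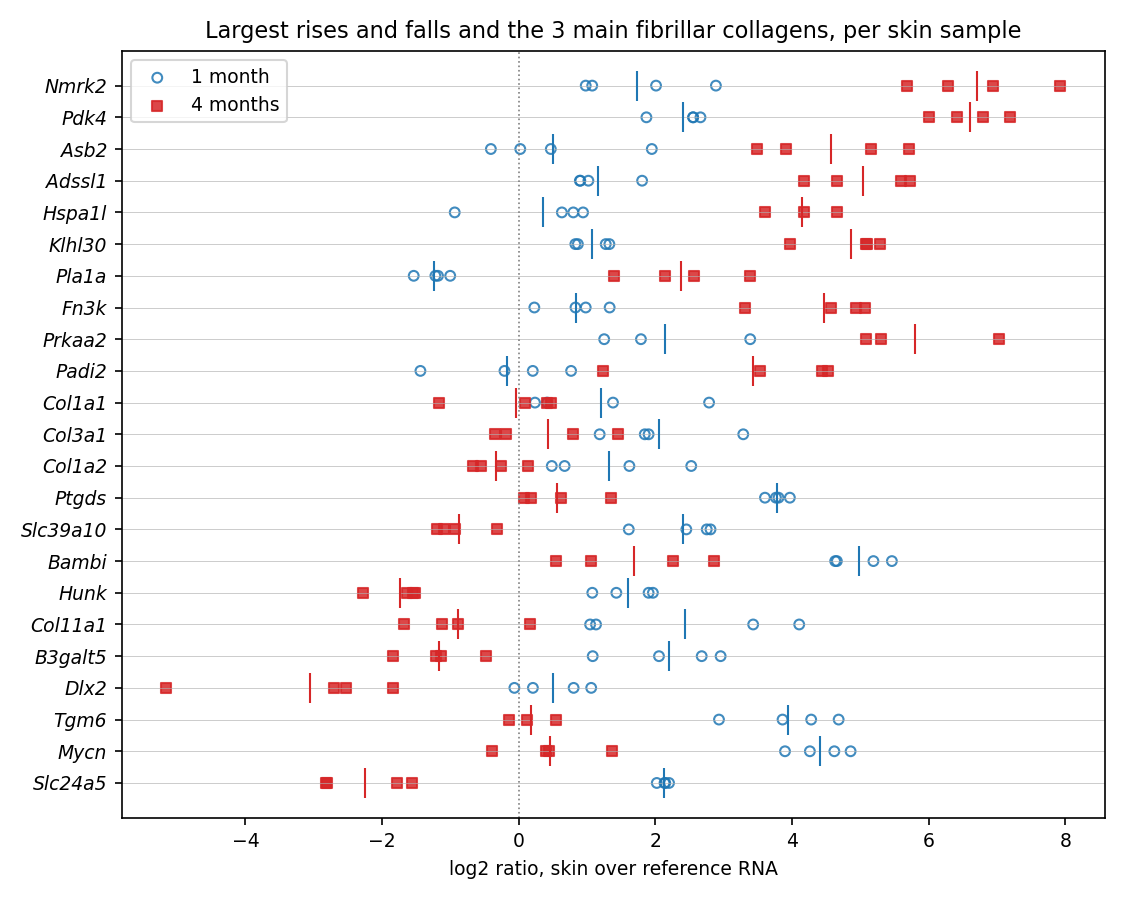
Log2 ratio of skin over reference (x axis) for the 10 largest rises, the 10 largest falls and Col1a1, Col1a2 and Col3a1 (y axis). Open circles are 1-month samples, filled squares 4-month samples and ticks their means. Slc24a5 lay near 2.12 at 1 month and near -2.24 at 4 months, while the ages overlapped for Col1a1 and Col3a1.

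In all, 979 of 13501 genes passed the limma test, 566 higher and 413 lower at 4 months, and 977 of them had ages that did not overlap. Over all tested genes 21.1% did not overlap, where chance gives 2.86% for 4 against 4 independent samples. If samples of 1 ID number are not independent, chance gives a larger share, which was not computed. Calls numbered 0 with limma on means per ID number (2 against 3, 2568 genes at an unadjusted p under 0.05), 2022 without the block and 204 with the skeletal muscle list as a covariate. They numbered 157 without 1-month sample 1, 473, 504 and 496 without 4-month samples 1, 2 and 3, and 2172 without 4-month sample 4. Without 1-month sample 1 the consensus correlation was 0.614, against 0.313 with all samples. A call lost without a sample need not mean a smaller difference. Without 1-month sample 1, Dlx2 was -3.77 (-3.62 with all samples) and Dlx1 -2.15 (-2.05), while Ctnnb1 was -1.11 (-1.28) and Flt1 1.19 (1.33). Of the 39 lists tested, 16 passed with the preset correlation, 8 higher and 8 lower, 4 with fry and 0 with camera at an estimated correlation (4 at an unadjusted p under 0.05). The exact permutation p of sample means is given unadjusted below, and adjusted over the 39 lists it was 0.0929 for each list at 0.0286, so no list passed by it. The number of lists is not beyond chance, since 11 of the 35 splits of the 8 samples into 4 and 4 passed at least as many.

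Cell division genes fell together. Of 45 measured members, 30 fell and 0 rose over all genes tested, and 43 fell adjusted over the list alone. The median was -1.61. Mki67, the proliferation antigen, fell from 0.01 ± 0.33 to -2.90 ± 0.78 (SD, n = 4 per age, adjusted p = 0.00858), as did Kif20a (-2.58), Ccna2, a cyclin of S phase and mitosis (-2.53), and Tpx2 (-2.23). The list passed at an adjusted p = 1.12e-33 with the preset correlation, at an adjusted p = 0.407 with an estimated correlation and at an adjusted p = 0.0147 with fry. Its mean per sample ran from -1.05 to -0.56 at 1 month and from -2.89 to -1.76 at 4 months (exact permutation p = 0.0286).

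Regulators of growing hair follicles were lower at 4 months in 24 of 26 measured members, and 10 passed. Adjusted over the list alone, 17 fell and 0 rose. Lef1, a transcription factor of Wnt signalling in the hair matrix, fell from 1.46 ± 0.18 to -1.70 ± 0.74 (SD, n = 4 per age). Dlx4 (-3.19) and Dlx1 (-2.05) fell beside Dlx2 (-3.62), and without 1-month sample 1 Dlx1 and Dlx2 did not pass (adjusted p = 0.0626 and 0.0594). The list median was -1.08 (adjusted p = 5.52e-12, adjusted p = 0.143 with an estimated correlation, and adjusted p = 0.00487 with fry). Its exact permutation p was 0.0286. Melanocyte genes were lower in 10 of 10 members, of which 3 fell, 5 adjusted over the list alone. Besides Slc24a5, Pmel, the melanosome fibril protein, fell by 2.52, and Tyrp1, an enzyme of melanin synthesis, fell by 2.16. Leaving out 1-month sample 1 or 4-month sample 1 or 3 ended both calls, as did 1-month sample 2 for Pmel and 4-month sample 2 for Tyrp1 (adjusted p from 0.0622 to 0.11). Gpnmb was -1.58 and did not pass, and it is also a macrophage gene. The pigment list had a median of -0.78 (adjusted p = 2.56e-06, adjusted p = 0.143 with an estimated correlation, adjusted p = 4.52e-05 with fry). Exact permutation gave p = 0.0286 for its sample means. The pigment median was -1.23 without 4-month sample 2 and -1.31 without 1-month sample 2 and 4-month sample 3. Hair shaft keratins and partners had 0 of 18 members past the limma test (2 at an unadjusted p under 0.05) and a median of -0.74, with 17 below 0. Padi3 (-2.39), Krt33b (-2.15), S100a3 (-1.35) and Krt36 (-1.30) did not pass, though Padi3 and Krt33b did without 4-month sample 4 (adjusted p = 0.0246 and 0.02). That list passed at an adjusted p = 0.0433, at 0.583 with an estimated correlation, and its exact permutation p was 0.0571. Leaving out 1-month sample 1, 3 or 4 or 4-month sample 1, 3 or 4 ended the call (adjusted p from 0.0602 to 0.182), as did muscle as a covariate (0.0509). Its median was not smaller with that covariate (-1.28), and it was -1.11 without 1-month sample 1 and -1.23 and -1.50 without 4-month samples 2 and 4. With quantile normalization it was -1.22 and with zeros kept -1.16, and the call held in 10 of the 22 settings of the preset test.

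Ribosomal protein genes were below 0 in 36 of 36 members. Over all genes 6 fell, and 20 adjusted over the list alone, with a median of -0.73. Rpl7 (-1.10), Rps24 (-1.09), Rps6 (-1.07) and Rps3 (-0.97) fell. All 4 lost their calls without 1-month sample 1, Rpl7, Rps24 and Rps3 without 4-month sample 1, 2 or 3, and Rps24 and Rps3 without 1-month sample 2 (adjusted p from 0.0587 to 0.146). The list passed at an adjusted p = 2.62e-12, at an adjusted p = 0.259 with an estimated correlation and at an adjusted p = 0.00487 with fry (exact permutation p = 0.0286). In the Wnt list 3 of 23 members fell and 0 rose, and adjusted over the list alone 6 fell and 1 rose. The 3 were Lef1, the stem cell receptor gene Lgr5 (-1.47) and Ctnnb1, which encodes beta-catenin (-1.28), and Wnt11 (-1.82) did not pass. Lgr5 and Ctnnb1 lost their calls without 1-month sample 1 and Ctnnb1 without 4-month sample 1, 2 or 3 (adjusted p from 0.0633 to 0.143), and Wnt11 passed without 1-month sample 2 (adjusted p = 0.0124). The Wnt median was -0.30 (adjusted p = 0.00581, adjusted p = 0.583 with an estimated correlation, exact permutation p = 0.0286). The Wnt call was lost without 4-month sample 1, 2 or 4 (adjusted p from 0.0553 to 0.0807) and without genes of more than 1 list (-0.22, adjusted p = 0.424), and held in 18 of 22 settings of the preset test. The Wnt median was -0.71, -0.20 and -0.57 without 1-month samples 1, 2 and 4, -0.64 with quantile normalization, -0.20 with zeros kept and -0.79 with muscle as a covariate. Of 20 sterol synthesis genes 1 fell, Stard4 (-1.24), a cholesterol carrier, and 0 adjusted over the list alone (limma, 2 at an unadjusted p under 0.05). The Stard4 call was lost without 1-month sample 1, 2 or 3 or 4-month sample 1, 2 or 3 (adjusted p from 0.0518 to 0.152). Sqle was -1.26, Srebf2 -0.61 and Fdft1 -0.49, and none of these 3 passed, though Sqle did without 4-month sample 4 (adjusted p = 0.00226). The sterol list median was -0.48 (adjusted p = 0.043, adjusted p = 0.799 with an estimated correlation, exact permutation p = 0.114). It lost its call without 1-month sample 1 or 3 or 4-month sample 1, 2 or 3 (adjusted p from 0.0599 to 0.206), and with muscle as a covariate (0.81). Its median was -0.31 without 1-month sample 1 and -0.12 with that covariate, and the call held in 10 of the 22 settings.

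The collagens that form fibrils had 8 of 10 members below 0, but 1 past the test, Col11a1, also when adjusted over the list alone. Col11a1 differed by ID number within 1 month, at 4.10 and 3.43 in samples 1 and 2 but 1.04 and 1.13 in samples 3 and 4. At 4 months it ran from -1.68 to 0.16. Over 21 settings its difference lay between -4.07 and -0.90, and its call held in 11 of them. Col3a1, the mutated gene, was 2.05 ± 0.88 at 1 month and 0.43 ± 0.85 at 4 months (SD, n = 4 per age), a difference of -1.64 with an adjusted p = 0.138. Col1a1 (-1.32, adjusted p = 0.226), Col1a2 (-1.65, adjusted p = 0.0984) and Col5a2 (0.37 ± 0.44 and -0.66 ± 0.45, adjusted p = 0.12) did not pass either, though Col1a2 did without 1-month sample 3 (0.0318) or 4-month sample 4 (0.0484). The probes of Col1a1 differed in size, at -1.96, -1.48 and -0.32. The list median was -0.88 (adjusted p = 0.0352, adjusted p = 0.511 with an estimated correlation, exact permutation p = 0.0286). The call was lost without 1-month sample 1 or 2 or 4-month sample 1 or 4 (adjusted p from 0.0523 to 0.0944), and that of Col11a1 without 1-month sample 1 or 2 or 4-month sample 1 or 2 (from 0.0523 to 0.0859). Without genes that stand in more than 1 list the median was -0.29 and the list did not pass (adjusted p = 0.24, range over the 22 settings of the preset test 0.00632 to 0.24). That setting took out Col1a1, Col1a2 and Col3a1, which also stand in the fibroblast list, so it tested only the other fibrillar collagens. On means per ID number the median was -0.30 (adjusted p = 0.0286), and with zeros kept it was -0.48 (0.0705). The collagen call held in 12 of these 22 settings.

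Other matrix lists did not pass, except that matrix glycoproteins passed as lower with muscle as a covariate (-0.35, adjusted p = 0.00869, and adjusted p = 0.872 in the planned fit with an estimated correlation). None of the 18 other collagen chains passed in limma (2 at an unadjusted p under 0.05), with Col16a1 at -0.86 (adjusted p = 0.105) and Col7a1, the anchoring fibril collagen, higher in mean, at 1.52 ± 1.22 and 3.12 ± 0.40 (SD, n = 4 per age, adjusted p = 0.113). Their median was -0.16 and the test pointed down, but the sample means differed by 0.05 the other way. None passed among 25 collagen processing genes (median -0.15, Sparc at -1.16 and the cross-linking enzyme gene Lox at -1.33), 36 matrix glycoproteins (-0.09, Thbs4 at 1.36 and Postn at -1.09) and 23 matrix proteases and inhibitors (0.37, Mmp9 at 1.21 and Mmp16 at -1.25), with 6, 9 and 6 members at an unadjusted p under 0.05. Without 4-month sample 4, Col16a1, Lox, Postn and Mmp16 passed (adjusted p from 0.00707 to 0.0356). Without 1-month sample 2, Col7a1 and Mmp9 passed (0.048 and 0.0173). In the TGF-beta list 1 of 25 members rose and 2 fell, with a median of -0.05 and an adjusted p = 0.371. These were Tgfb3 (1.39), a ligand of the pathway that was named after its value was seen, Bambi (-3.30) and Id2 (-0.98). Without 1-month sample 1 Bambi and Id2 lost their calls, and Id2 also without 1-month sample 2 or 4-month sample 1 or 2 (adjusted p from 0.059 to 0.148). The call of Tgfb3 was not followed over the left-out samples.

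**Figure D2:**
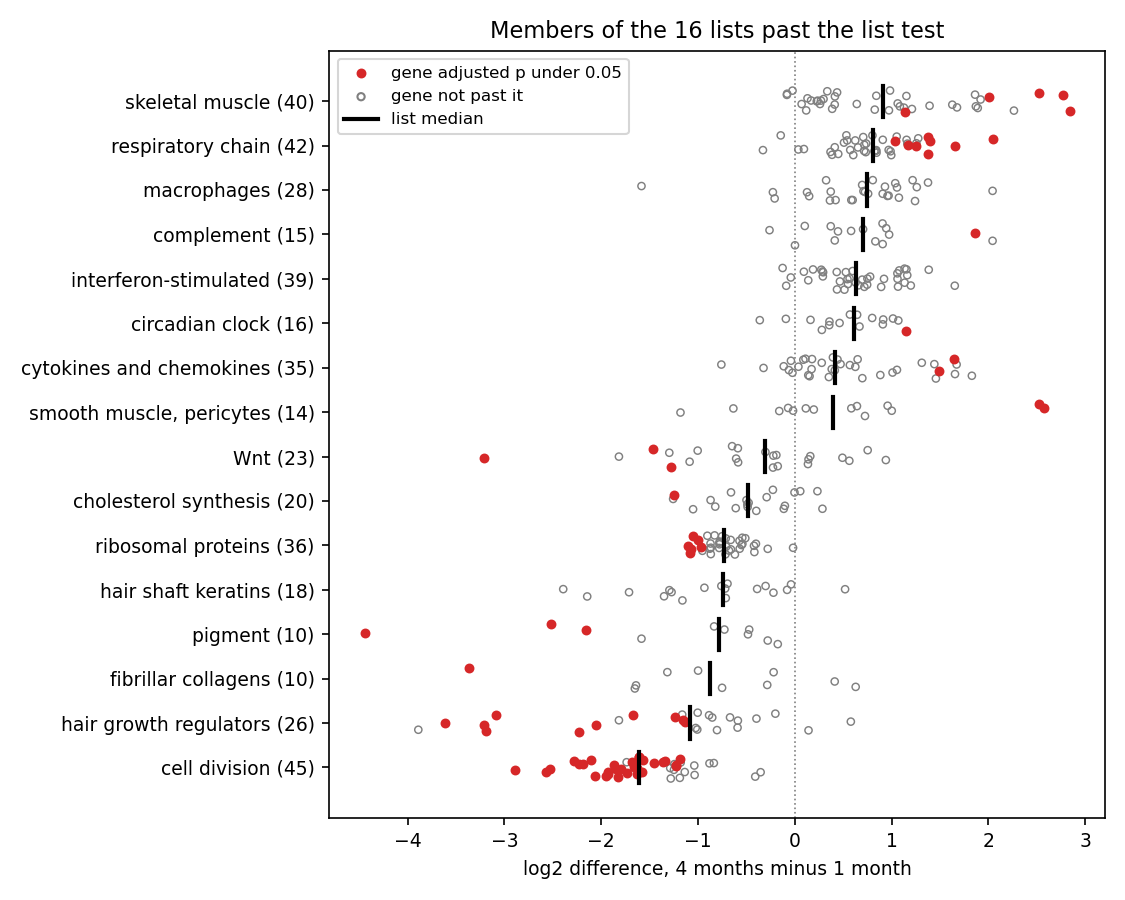
Log2 difference between 4 months and 1 month (x axis) for every measured member of the 16 lists past the list test (y axis, number of members in brackets). Filled points passed the test for single genes, open points did not, and black bars are list medians, from -1.61 for cell division to 0.91 for skeletal muscle.

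Genes of the respiratory chain were higher at 4 months. Of 42 subunits measured, 40 were above 0 and 8 rose, 21 adjusted over the list alone, with a median of 0.81. Ndufb8 of complex I rose by 1.65, Uqcrfs1 and Uqcrc1 of complex III by 1.40 and 1.38, and Atp5g1 of the ATP synthase by 1.37. All 4 lost their calls without 1-month sample 1, and Uqcrfs1 also without 1-month sample 2 or 4-month sample 1, 2 or 3 (adjusted p from 0.0549 to 0.109). The list passed at an adjusted p = 4.66e-10, at an adjusted p = 0.583 with an estimated correlation and not with fry (adjusted p = 0.0594), and its exact permutation p was 0.0286. Sample means were 0.48 to 0.56 at 1 month and 0.80 to 1.73 at 4 months.

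Skeletal muscle genes were above 0 in 37 of 40 members, and 5 rose, 9 adjusted over the list alone. These were the calcium channel gene Cacna1s (2.84), Eno3 (2.77), Des, which encodes desmin (2.52), Ldb3 (2.00) and Atp2a1 (1.14), the last named after its value was seen. The probes of Ldb3 gave 0.76 and 3.37, and Cacna1s lost its call without 1-month sample 1 (adjusted p = 0.0549). The call of Atp2a1 (adjusted p = 0.0463) was not followed over the left-out samples. The 35 members not past the test ran from -0.08 (Ckm) to 2.26 (Myh3). Several genes of the contractile apparatus lay near 0, among them Tnnc2 (-0.02), Myh1 (0.23) and Myh4 (0.30), named after their values were seen. The muscle median was 0.91 (adjusted p = 1.72e-05, adjusted p = 0.799 with an estimated correlation). Sample means of muscle genes overlapped, with 5.32 in 1-month sample 2, 3.73 to 4.16 in the other 1-month samples and 4.86 to 6.31 at 4 months (exact permutation p = 0.114). The muscle median was 0.56 without 1-month sample 1, 0.58 without 4-month sample 3 and 0.51 with quantile normalization. With the muscle mean as a covariate the respiratory chain median was 0.85 (adjusted p = 2.78e-09, range over the 22 settings of the preset test 5.79e-14 to 1.19e-07). In the planned fit with an estimated correlation the respiratory chain list did not pass (adjusted p = 0.583). Smooth muscle and pericyte genes had 2 of 14 members higher, Des and Lmod1 (2.58), and 3 adjusted over the list alone, while Cnn1 (1.00) and Synpo2 (0.96, probes 2.01 and -0.03) did not pass. Lmod1 lost its call without 1-month sample 1 or 4-month sample 2 or 3 (adjusted p from 0.0539 to 0.0936), and Synpo2 passed without 4-month sample 4 (0.00564). The smooth muscle median was 0.39 (adjusted p = 0.0451, adjusted p = 0.684 with an estimated correlation, exact permutation p = 0.0286). That call was lost without 1-month sample 2 or 3 or 4-month sample 1, 2 or 4 (adjusted p from 0.0604 to 0.146). Its median was 0.088 and 0.22 without 1-month samples 2 and 3, 0.21 without 4-month sample 1 or 2, and 0.24 without 1-month sample 2 and 4-month sample 3 (adjusted p = 0.055). It was 0.15 with quantile normalization (0.0885) or zeros kept (0.0292), and 0.20 without genes of more than 1 list (0.256), and the call held in 8 of the 22 settings.

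**Figure D3:**
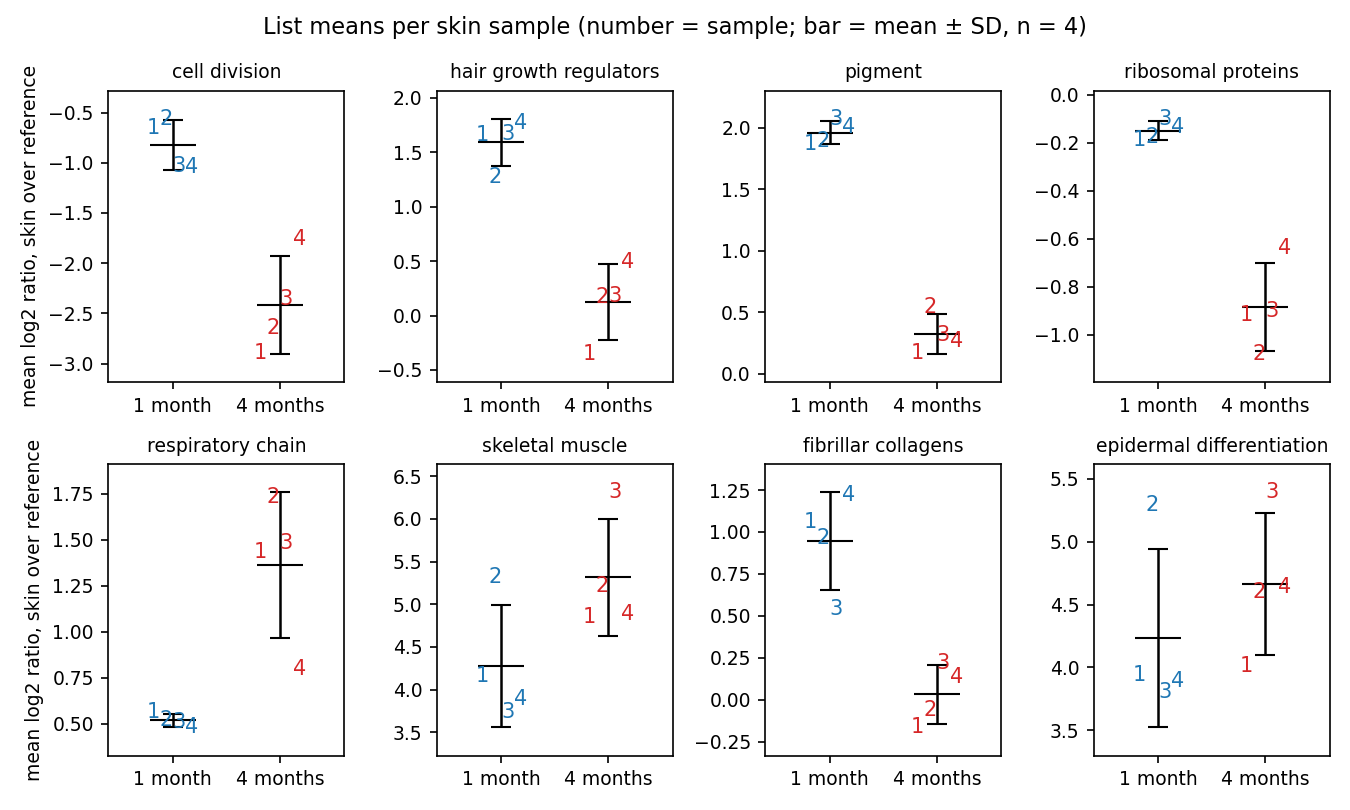
Mean log2 ratio of skin over reference (y axis) of 8 gene lists in each skin sample at 1 and 4 months (x axis). Digits give the sample and bars the mean ± SD of 4 samples. The ages did not overlap for cell division, hair growth, pigment, ribosomal, respiratory chain and fibrillar collagen lists, and did for skeletal muscle and epidermal differentiation.

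Macrophage, interferon, complement and chemokine lists were higher at 4 months mostly without single genes past the test. For macrophages 0 of 28 members passed in limma (12 at an unadjusted p under 0.05) and 25 were above 0, with a median of 0.74 (adjusted p = 0.00554, adjusted p = 0.758 with an estimated correlation). C1qb (2.04), Itgam (1.26), Cd14 (1.22) and Lyz1 (1.04) did not pass, though C1qb and Itgam did without 1-month sample 4 (adjusted p = 0.0454 and 0.0355) and Cd14 without 4-month sample 2 (0.0273). The exact permutation p was 0.114. Interferon-stimulated genes had 0 of 39 members past the limma test (6 at an unadjusted p under 0.05), 36 above 0 and a median of 0.63 (adjusted p = 0.0075, adjusted p = 0.799 with an estimated correlation, exact permutation p = 0.257). Oas2 (1.38), Oasl1 (1.16), Igtp (1.08) and Irgm1 (0.92) did not pass. Complement genes had 1 of 15 higher, C4b (1.86), and 5 adjusted over the list alone, with C1s1 (0.94) and Cfp (0.91) not past the test. C4b lost its call without 1-month sample 1 or 2 or 4-month sample 1 or 3 (adjusted p from 0.0545 to 0.113), with differences of 1.67 to 1.93. Cfp passed without 4-month sample 4 (0.0344). Their median was 0.70 (adjusted p = 0.00911, adjusted p = 0.583 with an estimated correlation, exact permutation p = 0.0286). Of 35 cytokine and chemokine genes, Ccl9 (1.65) and the eosinophil attractant gene Ccl24 (1.49) rose, 3 adjusted over the list alone, while Ccl2 (1.67) and Csf1 (1.05) did not pass. Both calls were lost without 1-month sample 1 or 2 or 4-month sample 1 or 3, and that of Ccl24 also without 4-month sample 2 (adjusted p from 0.0558 to 0.185). Ccl2 passed without 4-month sample 2 or 4 (0.0408 and 0.0211). That median was 0.41 (adjusted p = 0.0352, adjusted p = 0.799 with an estimated correlation, exact permutation p = 0.114). Each of the 4 calls was lost without 4-month sample 4 (adjusted p from 0.0807 to 0.266). The interferon call was also lost without 1-month sample 3 or 4 or 4-month sample 1, the complement call without 4-month sample 3, and the cytokine call without 1-month sample 1 or 3 or 4-month sample 3 (adjusted p from 0.0526 to 0.251). With muscle as a covariate the medians were 0.51 for macrophages (adjusted p = 0.244), 0.35 for interferon (0.052), 0.31 for complement (0.345) and 0.063 for cytokines (0.813). The interferon median was 0.34 without 4-month sample 1 and 1.01 with Xist as a covariate, and the cytokine median 0.27 without 1-month sample 1 and 0.18 with zeros kept (0.0598). The complement median was 0.39 without 4-month sample 3, 0.32 with quantile normalization (0.112) and 0.45 with zeros kept.

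Among 16 clock genes 14 were above 0 and 1 rose, Bhlhe40 (1.15), a repressor in the circadian loop, also adjusted over the list alone. Bhlhe41 (1.07), Cry2 (1.01) and Nr1d1 (0.91, probes 1.45 and 0.34) did not pass, though Cry2 and Nr1d1 did without 4-month sample 4 (adjusted p = 0.0182 and 0.0173). The Bhlhe40 call was lost without 1-month sample 1 or 2 or 4-month sample 1 or 2 (adjusted p from 0.0573 to 0.1). The clock median was 0.61 (adjusted p = 0.0208, adjusted p = 0.511 with an estimated correlation, exact permutation p = 0.0286), and without 4-month sample 2 the adjusted p was 0.0557. On means per ID number it was 0.0516. The clock median was 0.36 with zeros kept or with muscle as a covariate. The hour of sampling is not given in the labels.

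Lists of other skin cells did not pass in the planned fit, where the epidermal differentiation, fibroblast and keratin-associated lists each had an adjusted p = 0.872 with an estimated correlation. Epidermal differentiation genes had 1 of 36 members higher, Sbsn (1.09), and 0 adjusted over the list alone (limma, 5 at an unadjusted p under 0.05), while Lce1g of the cornified envelope (2.13) did not pass. Their median was 0.39 (adjusted p = 0.279). The list passed without 1-month sample 2 (0.0144) and without that sample and 4-month sample 3 (0.59, adjusted p = 0.00517), and with muscle as a covariate it passed in the other direction, at -0.40 (0.00581). The medians were 0.03 for 15 basal keratinocyte genes (Lamb3 at 1.30, Dst at 0.85), 0.09 for 13 stress keratins and alarmins (Il33 at 1.65, Tslp at 1.04) and 0.14 for 25 adipocyte genes (Slc2a4 at 1.79, Plin4 at 1.28), all 3 below 0 after quantile normalization, with 0 members past the limma test in each (4, 0 and 2 at an unadjusted p under 0.05). Fibroblast genes had a median of -0.06, with 0 of 24 past the test (2 at an unadjusted p under 0.05, Col1a2 and Col3a1). With muscle as a covariate the fibroblast list passed as lower, at -0.53 (adjusted p = 0.00581). In the sebaceous list 1 of 13 rose, Ldhb (1.54), and 2 adjusted over the list alone, with Acsbg1 at 1.15 and a median of 0.34. Among 18 genes of resting follicles Lgr5 (-1.47) fell and Nfatc1, a regulator of follicle stem cells (1.34), rose, while 3 fell and 1 rose adjusted over the list alone (median -0.11). Keratin-associated proteins had 0 of 18 past the test (1 at an unadjusted p under 0.05) and a median of -0.33 (Krtap4-6 at -0.66), but passed as lower with Xist as a covariate (-0.93, adjusted p = 0.0138). The sign was the other way with muscle as a covariate (0.93, adjusted p = 0.0541), on means per ID number (0.11) and without 1-month sample 3 (0.078), none past the test. Their sample means differed by ID number within 1 month, at 1.52 and 1.05 in samples 1 and 2 but 4.24 and 4.16 in samples 3 and 4. At 4 months they ran from 1.02 in sample 1 to 3.92 in sample 4. Leaving out 1 sample ended the calls of Sbsn and Ldhb (1-month sample 1 or 2 or 4-month sample 1, 2 or 3, and for Ldhb 1-month sample 4), Nfatc1 (1-month sample 1 or 2 or 4-month sample 2 or 3) and Lgr5 (1-month sample 1), with adjusted p from 0.0504 to 0.139. Without 4-month sample 4, Lamb3, Lce1g, Slc2a4 and Plin4 passed, as did Lce1g without 1-month sample 2 (adjusted p from 0.0339 to 0.049).

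Of 16 endothelial genes 15 were above 0 and 1 rose, the VEGF receptor gene Flt1 (1.33), also adjusted over the list alone, with Tek at 0.78 and a median of 0.40 (adjusted p = 0.0973). For antigen presentation genes 0 of 12 passed in limma (4 at an unadjusted p under 0.05) and the median was 0.81 (adjusted p = 0.124), with Batf3 at 1.37 and H2-DMa at 1.17. Immediate early genes had 2 of 24 higher, Nr4a1 (2.69) and the phosphatase gene Dusp1 (1.62), also adjusted over the list alone, with a median of 0.35 (adjusted p = 0.0973). These 3 lists passed without 1-month sample 2 (endothelium, 0.0472), 1-month sample 4 or 4-month sample 2 (antigen presentation, 0.0241 and 0.0429) and 1-month sample 4 or 4-month sample 1 (immediate early, 0.0458 and 0.0253). They also passed on means per ID number (adjusted p = 0.0389, 0.0303 and 0.0421). In the planned fit with an estimated correlation none of the 3 passed (adjusted p = 0.583, 0.799 and 0.872). Flt1 and Dusp1 lost their calls without 1-month sample 1 or 4-month sample 1, 2 or 3 and Nr4a1 without 1-month sample 1 (adjusted p from 0.0513 to 0.159), while Batf3 passed without 4-month sample 4 (0.0278). None passed among 12 T and NK cell genes (median 0.04, Cd96 at 0.56), 8 B cell genes (0.08, below 0 after quantile normalization, Tnfrsf17 at -0.65), 8 neutrophil and mast cell genes (-0.11, Fcer1a at 0.74, Kit at -0.48), 5 red cell genes (-0.25, Alas2 at -0.79) and 6 embryo or testis genes (0.16, Dppa5a at 0.80), where Alas2 alone was at an unadjusted p under 0.05. None of 9 Schwann and nerve genes passed (1 at an unadjusted p under 0.05, median -0.18, Mbp at 0.87, Gfra3 at -1.19), and their test pointed up with an estimated correlation. The 17 growth genes had a median of 0.07, below 0 after quantile normalization, but a mean of -0.16 and a test that pointed down (Plagl1 at -1.44, Igf2bp3 at -0.95), and 0 passed (1 at an unadjusted p under 0.05).

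Levels against the reference RNA are given here in the turned sign. The epidermal, muscle, cell division and B cell lists helped to set that sign, so the side of 0 on which they lie is no result. The mean log2 ratio of the epidermal differentiation list was 4.23 ± 0.71 at 1 month and 4.66 ± 0.57 at 4 months (SD, n = 4 per age). Skeletal muscle genes stood at 4.28 ± 0.72 and 5.32 ± 0.68, adipocyte genes at 2.96 ± 0.44 and 3.22 ± 0.73, and fibroblast genes at 1.14 ± 0.34 and 0.94 ± 0.37. Fibrillar collagens stood at 0.95 ± 0.29 and 0.03 ± 0.18, pigment genes at 1.96 ± 0.09 and 0.32 ± 0.16, and cell division genes at -0.82 ± 0.25 and -2.41 ± 0.49. Xist was above the reference in 1-month samples 1 (2.27) and 2 (1.67) and 4-month sample 1 (1.08) and between -4.06 and -2.96 in the other 5, with the Y-linked gene Kdm5d the other way round. Samples of 1 ID number were alike in this, and the sexes, as read from Xist and Kdm5d, were unevenly spread over the ages.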

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

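All tests of explanations in this part were chosen after the results were seen. Values that stood apart were looked for in 304 groups of 4 samples, as a highest or lowest sample whose gap to the next exceeds the 95% point of Dixon's test. There were 25 (8.22%), 20 of 226 for named genes and 5 of 78 for lists, where chance gives about 1 in 20. Of these, 6 genes and 3 lists were in 1-month sample 2, which also stood apart on the second principal component. In that sample, Adssl1 was 1.81 (others 0.89 to 1.02), Hba-a2 6.41 (4.36 to 4.64), Mmp16 0.24 (-0.21 to -0.19), Mzb1 -3.51 (-4.46 to -4.45), Pmel 5.55 (3.77 to 3.94) and Srebf2 -0.81 (-0.24 to -0.16). Its epidermal differentiation mean was 5.29 (3.80 to 3.94), its B cell mean -1.28 (-2.49 to -2.41) and its cytokine mean 0.12 (-0.66 to -0.55).

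In 1-month sample 1, Ccl24 was -1.78 (others -1.14 to -1.0), Hspa1l -0.94 (0.63 to 0.94), Igf2bp3 -3.64 (-2.09 to -2.0) and Plagl1 3.11 (1.48 to 1.72). In 1-month sample 4, Col16a1 was 0.81 (-0.04 to 0.04), Lox -1.17 (-2.73 to -2.54), Pdk4 1.87 (2.55 to 2.66) and the mean of resting follicle genes 1.22 (0.96 to 1.00). In 4-month sample 1, Hunk was -2.28 (-1.63 to -1.53), Irgm1 1.16 (-0.29 to -0.07), Klhl30 3.97 (5.07 to 5.29) and the Wnt mean 0.55 (1.01 to 1.03). In 4-month sample 2, Cd14 was -2.91 (-1.75 to -1.63). In 4-month sample 4, Col16a1 was -0.26 (-0.83 to -0.76), Sqle -0.27 (-2.16 to -1.99) and Stard4 -0.36 (-1.40 to -1.27).

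Chance was tested by splitting the 8 samples into 4 and 4 in all 35 ways. For genes, 1 split gave a count as large as the real one, the real one itself with 979. The highest of the others had 3, which argues against chance if the 8 samples are exchangeable. Samples of 1 ID number may not be, and by number the smallest exact p is 0.1, with 0 genes past limma on means per number (2568 at an unadjusted p under 0.05). For lists with the preset correlation, 11 splits passed at least the real number of 16, and the highest of the others passed 22, so chance cannot be excluded for the number of lists. Each of the 35 splits passed at least 4 lists.

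The cell division, hair growth and pigment lists were all lower at 4 months, in samples whose sex was uneven between the ages. With Xist as a covariate each list passed with the preset correlation (in the planned fit with an estimated correlation none did, adjusted p = 0.407, 0.143 and 0.143) and kept at least 95.4% of its median, and after quantile normalization at least 91.9%, while other genes moved, which argues against sex or array scaling as the whole cause. A lower share of epidermal cells would lower other epidermal genes alike, but 51 of these outside the 3 lists had a median of 0.33 (spread 0.19), and of -0.43 (spread 0.36) with muscle as a covariate, against list medians of at most -0.78 and -0.94. With that covariate the epidermal differentiation list passed as lower in the preset test (-0.40, adjusted p = 0.00581). The 51 genes were epidermal differentiation and basal keratinocyte genes, so they do not test the share of hair follicle or pigment cells alone. A difference that comes with age or with ID number, such as another phase of the hair cycle, may underlie the pattern and was not tested.

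Respiratory chain genes were higher at 4 months, when skeletal muscle genes were higher too with the preset correlation. The muscle list did not pass with an estimated correlation (adjusted p = 0.799), and its sample means overlapped between the ages. With the muscle mean as a covariate the respiratory chain list kept 104% of its median and passed with the preset correlation (adjusted p = 0.583 with an estimated correlation in the planned fit), while the muscle list lost its own call, as that setting must bring about. After quantile normalization it kept 83.8%. At each age the muscle mean was highest in 1 sample, 1-month sample 2 (5.32) and 4-month sample 3 (6.31). Those 2 samples were also highest in the epidermal differentiation mean (5.29 and 5.39) and apart on the second principal component. The muscle covariate may thus follow another difference between samples, so it decides nothing about a larger share of muscle, which stays open. The value after quantile normalization argues against array scaling as the whole cause. None of the 4 named subunits passed with the muscle covariate. Age itself stays open and untested.

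Fibrillar collagens were lower at 4 months as a list with the preset correlation, in 12 of the 22 settings besides the planned one, but not with an estimated correlation (adjusted p = 0.511) or fry (adjusted p = 0.0594). A lower share of fibroblasts would lower their other genes alike, but the 21 other members of the fibroblast list had a median of 0.071 (spread 0.21), and of -0.39 (spread 0.27) with muscle as a covariate, against collagen medians of -0.88 and -1.15, which argues against it as the whole cause but not as a part, since the whole fibroblast list passed as lower with that covariate (-0.53, adjusted p = 0.00581). With the muscle mean as a covariate the collagen median was 131% of its size, but the list did not pass, with an adjusted p of 0.075 in place of 0.0352. The median SE of a member went from 0.47 to 0.61 and the quartiles from -1.56 and -0.24 to -1.44 and -0.27. Why the list lost its place among the other genes was not tested. A larger share of muscle would shrink the collagen median under that covariate, but the covariate may follow another difference between samples, as given above. A larger share would also lower genes of other cells alike. Without the covariate, however, the 21 fibroblast genes (0.071) and 51 epidermal genes (0.33, spread 0.19) were not lower. Both medians argue against a larger share of muscle as the whole cause, while the lost call leaves it open as a part. Age and the course of the disease stay open and untested, and no wild-type skin was analysed here.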

How the results depend on the processing

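The covariates, the kept zeros, the left-out repeated values and the fit without 2 samples were chosen after the data were seen, and the other alternatives were planned. Against 979 genes, limma called 2022 without the block, 0 on means per ID number (2568 at an unadjusted p under 0.05), 581 with the ID suffix as a replicate block, 2177 from 10 arrays with the sample as block, 204 with muscle as a covariate (164 shared) and 593 without 1-month sample 2 and 4-month sample 3 (469 shared). The number of samples fell to 2 against 3 for ID numbers, and the cause was not tested for the others. Leaving out 1 sample gave 157 (1-month sample 1) to 2172 (4-month sample 4). Other settings gave 656 to 1297. The suffix 1 minus suffix 2 difference correlated across 12397 genes at 0.43 between the ages, whose ID numbers differ. Lists passing numbered 10 without genes of more than 1 list, 4 with fry, 0 with an estimated correlation, 8 (without 4-month sample 4) to 16 with 1 sample left out, and 12 to 18 otherwise, against 16. Cell division, hair growth, pigment, ribosomal and respiratory chain lists kept direction and call in 22 of 22 settings of the preset test, with highest adjusted p of 7.93e-26, 7.4e-07, 0.00028, 2.78e-09 and 1.19e-07. These lists did not pass with an estimated correlation. The preset test passed at least 4 lists in each of the 35 splits of the samples, so kept calls do not exclude chance. Skeletal muscle kept direction and call in 21 settings, losing them with itself as covariate (-0.16), as constructed. Calls were kept in 20 settings for macrophage and clock, 18 for complement and Wnt, 17 for interferon, 15 for cytokines, 12 for fibrillar collagens, 10 for sterol and hair shaft and 8 for smooth muscle lists, whose other settings kept the direction. The direction check on epidermal genes held with arrays centred. Lists that had not passed did so, at adjusted p given, for matrix glycoproteins (muscle covariate, -0.35, 0.00869), fibroblast (muscle, -0.53, 0.00581), red cell (muscle, -1.18, 0.00581), keratin-associated (Xist, -0.93, 0.0138), epidermal differentiation (replicate block, 0.69, 0.0375, and without the 2 samples, 0.59, 0.00517), antigen presentation (ID means 0.0303, replicate block 0.00284), endothelium (ID means 0.0389, Xist 0.0228, without the 2 samples 0.0421) and immediate early (ID means 0.0421, quantile 0.0377, without the 2 samples 0.0428). Of 121 named genes, 56 lost their call on means per ID number, 35 with muscle as a covariate, 31 of 118 without 1-month sample 1 and 23 with zeros kept. With the replicate block 16 lost their call and 3 gained one. The following medians changed sign or, where 0 is given, reached 0, none past the threshold unless said. With muscle as a covariate: other collagens 0.085, keratin-associated 0.93, epidermal differentiation -0.40 (past it, adjusted p = 0.00581, range over the 22 settings of this test 0.00517 to 0.996), basal -0.58, T and NK -0.29, B cell -0.69, growth -0.38, embryo or testis -0.39, and gene Mzb1 -0.12. With quantile normalization: basal -0.27, stress keratins -0.25, adipocyte -0.21, B cell -0.010, growth -0.21. On means per ID number: keratin-associated 0.11, T and NK -0.0061, B cell -0.063, neutrophil and mast 0.0015, growth -0.020. With the replicate block: collagen processing 0.033, neutrophil and mast 0.18, growth -0.028. With zeros kept: collagen processing 0.001, T and NK 0, B cell -0.029, neutrophil and mast 0.058, Schwann 0.076. Without genes of more than 1 list: resting follicle 0.024, neutrophil and mast 0.11, fibroblast 0.0038. Without the 2 samples: neutrophil and mast 0.035, fibroblast 0.00065, growth -0.24, and gene Hba-a2 0.088. With the first array, T and NK -0.00073. With Xist, fibroblast 0.036. With the probe of the highest mean, gene Igf2bp3 0.49. Leaving out 1 sample gave medians, lowest and highest, of -0.37 and 0.076 for other collagens, -0.14 and 0.091 for collagen processing, -0.21 and 0.052 for TGF-beta, -0.86 and 0.078 for keratin-associated, -0.22 and 0.12 for resting follicle, -0.083 and 0.77 for epidermal differentiation (past it at 0.77, without 1-month sample 2), -0.16 and 0.39 for basal, -0.11 and 0.56 for stress keratins, -0.12 and 0.43 for adipocyte, -0.062 and 0.42 for T and NK, -0.27 and 0.29 for B cell, -0.45 and 0.16 for neutrophil and mast, -0.24 and 0.10 for Schwann, -0.12 and 0.075 for fibroblast, -0.59 and 0.12 for red cell, -0.21 and 0.19 for growth, -0.061 and 0.36 for embryo or testis, and -0.65 and 0.16 for gene Hba-a2. The cause of these changes was not tested. Signal over background, which limits weak probes, was not analysed here.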

Other observations

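The genes in this part were chosen after their values were seen, and were not refitted under the alternatives. Of the 10 hair growth regulators that fell, 6 have not been described. They were the hair keratin regulator Hoxc13 (-3.09), Bmp8a (-2.23), the vitamin D receptor gene Vdr (-1.68), Bmp4 (-1.24), Msx1 (-1.15) and Shh, a signal of the growing follicle (-1.14). Hoxc13 had an SE of 0.73 and an adjusted p = 0.0362, and Vdr an SE of 0.44 and an adjusted p = 0.049, with 4 samples per age in limma. Among respiratory chain genes the other 4 that rose were Cox7a1, the heart and muscle isoform of a cytochrome oxidase subunit (2.05), Cycs, which encodes cytochrome c (1.26), Sdhb of complex II (1.17) and Atp5g3 (1.04). The 2 other ribosomal protein genes that fell were Rpl3 (-1.05, adjusted p = 0.0463) and Rpl32 (adjusted p = 0.043).

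On the Y chromosome, Eif2s3y was at -4.17 in 1-month sample 2 and -3.56 in 4-month sample 1, was not measured in 1-month sample 1, and lay between 2.30 and 2.94 in the other 5 samples. Kdm5d lay between -2.42 and -1.96 in the 3 samples with Xist above the reference and between 0.01 and 0.80 in the others. Uty did not separate them, at -1.81 and -0.16 on the arrays of 1-month sample 1, 0.08 in 1-month sample 2 and 0.23 in 4-month sample 1, against -0.24 to 0.98 on the other arrays.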
